A study of Caenorhabditis elegans with 8 samples.

How the data were processed

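RNA immunoprecipitation followed by sequencing (RIP-seq) was performed on young adult Caenorhabditis elegans grown at 25 °C. Worms were crosslinked with 2% formaldehyde for 30 min, per the labels' protocols. The samples came from a strain that expresses MSTR-1 with a FLAG tag from its own gene (sequence name F22D6.2) and from the wild-type strain N2, which carries no FLAG tag. Each strain had an immunoprecipitate (RIP) and an input of whole worm lysate, giving 4 groups of 2 biological replicates and 8 samples.

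The data analysed here were 1 deposited table of genomic regions specific to the tagged strain. Per the submitters' processing notes, STAR and deepTools were used, with no version given. The peak caller, its control library, the genome build and the rule by which regions were called strain-specific are not given in the sources used here. The deposited table has no header. Its first 10 columns have the layout that MACS2 writes for narrow peaks, and every region name carries the second RIP replicate of the tagged strain. Per region, the authors' table gives a position, a score, a fold enrichment (a ratio of treatment over control at the summit), a −log10 p-value, a −log10 q-value and a summit offset. The deposited score equalled 10 times the −log10 q-value rounded down in all 1207 regions. An 11th column holds 0, 1 or 2 with no label. The table holds no value per library, so no depth per sample, replicate spread or test between libraries could be had, and the planned interaction test of RIP over input between strains was not run. The folds and q-values below are the authors' own values for each region.

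The counts behind each fold were recovered from the deposited fold and p-value. The fold was taken as (pileup + 1) / (control + 1) and the p-value as the Poisson probability, under the control level, of more reads than the pileup. Solving both for each region gave pileups within 0.02 of a whole number in 1166 of 1207 regions (96.6%), and in all 1061 regions with pileups under 300. Above that, the printed decimals limit the precision. The lowest control level was 13.49 reads, shared by 304 regions, as a caller's minimum background level gives. Between this floor and a level of 60, 555 of 620 control levels (89.5%) lay within 0.02 steps of a whole multiple of 0.638, so 1 control read counted as 0.638 reads of the treatment. On simulated values rounded as in the table, 100% of 839 regions with pileups under 300 were recovered. The simulated values were made with the same formulas, so this tests the solving and the rounding only. It cannot show that the caller used these formulas. Intervals on pileups are exact 95% Poisson intervals. These and the binomial intervals cover counting error only, since reads are not independent molecules.

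Regions were assigned to genes by position, with 1 shared base as the minimum, against the RefSeq gene table of WBcel235 (46926 genes, of which 19983 are protein-coding). The fit to this assembly was tested by shifting all regions. Strand is given neither for the regions nor in the gene table, so genes on opposite strands cannot be told apart, and 60 regions overlapped 2 protein-coding genes. The gene table has starts and ends but no exons. The planned placement in UTR, coding sequence and intron was therefore not run, gene span replaced exonic length, and the number of protein-coding genes replaced exonic bases as the chromosome background. Region positions are 1-based and as deposited.

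Genes with a region were compared with 20 gene lists fixed before the data were examined, as were the tests and the rule for named genes. The 12 members of the mitochondrial genome list carry other symbols in the gene table, leaving 19 lists with at least 5 members for the test. Each used a two-sided Fisher's exact test against all protein-coding genes, with Benjamini-Hochberg adjustment over the 19 lists. That background includes genes not expressed in these worms, because no expression values were used here to restrict it. In simulated gene sets, 100 per weight, lists whose members had a weight of 4 were called in 94.2% of cases and those with a weight of 8 in 100%. Unplanted lists were called in 0.607% of cases in those sets, and in 0.158% when nothing was planted. The planted lists had 62 to 174 members, so the rates for planted lists do not cover smaller ones. All other genes had equal weight, so none of these rates covers an effect of expression or gene span. Chromosomes were compared with a chi-square statistic with a p-value simulated from 100000 draws, and 1 chromosome at a time with Fisher's exact test. Region placement was set against 1000 random placements on the same chromosome, and gene span against 100000 random gene sets. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

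Named genes were the 25 with the highest-fold region, up to 4 members of each list by fold, and the tagged gene itself. Where others are named, the text says that they were chosen after their values were seen. Alternatives were the 603 regions with the highest folds, merging of regions, gene sets matched on span, at least 0.5 of a region inside the gene, and genes with at least 2 regions. Those added after seeing the data left out regions over 2 genes, or kept regions by the unlabelled value or by control level, or changed how genes and chromosomes were counted. The use of the 603 regions for gene span was also added then.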

Results

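Affinity purification of FLAG-tagged MSTR-1 asks which RNAs associate with MSTR-1, with untagged N2 worms as the background. The deposited outcome was a list of 1207 regions specific to the tagged strain, on chromosomes I to V and X and none on the mitochondrial genome. The regions had a median width of 642 bp (quartiles 390.5 and 1089.5, range 230 to 14654). Their numbering runs to 1464, so 257 numbers (17.6%) do not occur in the list. The name of every region carries the second RIP replicate of the tagged strain, and each region has 1 set of values. No value below therefore has a replicate error, and the other libraries were not analysed here.

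Enrichment was moderate. The median of the authors' fold over control was 2.1 (quartiles 1.78 and 2.49, range 1.11 to 5.66). A fold of at least 2 was reached by 705 regions (58.4%), at least 3 by 129, and at least 4 by 23. The authors' −log10 q ran from 1.3 to 289.6 with a median of 5.41. The recovered read pileup at the summit had a median of 55 (quartiles 38 and 110, range 26 to 3128), and the control level a median of 23 with a maximum of 2215.

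The size of fold that passed the authors' threshold depended on this coverage. In the 304 regions at the control floor of 13.49 reads, the lowest fold was 1.86 and the median 2.42. In the 108 regions with a control level above 300, the lowest was 1.11 and the median 1.54. Folds under 1.86 therefore occur in the list only above the floor.

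The regions lay in genes. All 1207 overlapped an annotated gene and 1199 a protein-coding one. The midpoint was inside a protein-coding gene for 1197 regions (99.2%), against a mean of 62.7% and a maximum of 67.2% in 1000 random placements (permutation p = 0.001, the smallest they can give). Regions derived from RNA can only lie in transcribed sequence, so this difference says nothing about MSTR-1. Whole regions lay inside a protein-coding gene in 1187 cases. With shifts in steps of 5 bp near 0, this number was highest at −5 bp, with 1190, and it fell to 1040 after a shift of −100 bp and to 999 after a shift of 100 bp. On each chromosome the best shift was within 15 bp of 0, which fits the coordinates to WBcel235, although no build is named for them.

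**Figure D1:**
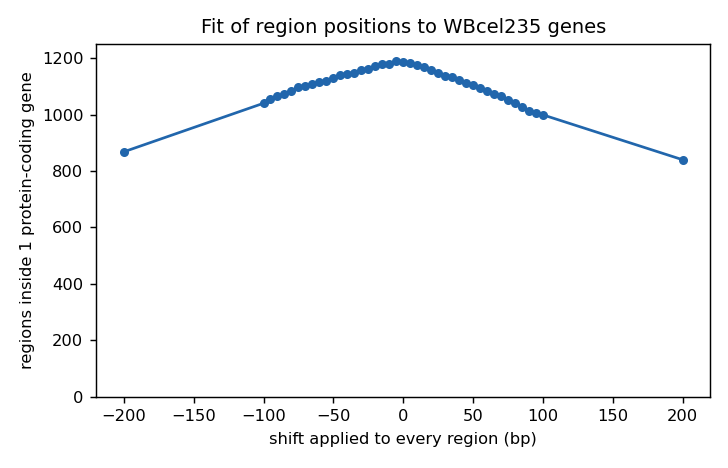
Number of the 1207 regions that lie wholly inside a protein-coding gene of WBcel235 (y axis) after all regions were shifted by the distance on the x axis (bp). The number is 1187 without a shift and highest, at 1190, with a shift of −5 bp, and falls to 1040 and 999 at −100 and 100 bp.

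The tagged protein's own gene carried a region. mstr-1 (F22D6.2), on chromosome I, had 1 region at 7080511 to 7081417 with a fold of 2.26 and a −log10 q of 9.78. Its summit held 88 reads (95% interval 70.6 to 108) against a control level of 38.3, and it ranked 468th of 1207 by fold. No other protein-coding gene overlapped it. Of all protein-coding genes, 954 of 19983 (4.77%, exact 95% interval 4.48 to 5.08) carried a region.

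The regions with the highest folds were in genes of varied function. ZC247.1 led with a fold of 5.66 at chromosome I, 10264454 to 10264935, from 81 reads (64.3 to 100.7) over the control floor of 13.49. It was followed by nspg-13 (5.56, 122 reads) and fat-4 (5.52, 79 reads), which encodes a fatty acid desaturase. hpo-34 had 5.25 and the collagen gene col-162 had 5.16, from 117 reads over 21.8. Below these came C17H12.8 (4.76), mca-3 (4.72), which encodes a plasma membrane calcium ATPase, rbm-7 (4.65), upb-1 (4.62) and cytb-5.1 (4.42), which encodes a cytochrome b5. The region of rbm-7 also overlapped Y37D8A.19. D1054.10 reached 4.22, and rle-1, which encodes a ubiquitin ligase, ell-1 and T04F3.1 each had 4.21 from 60 reads over the floor. H40L08.2 had 4.16, in a region shared with H40L08.7. The values of epc-1, the astacin protease gene toh-1, the saposin-like gene spp-8 and F09B12.3 were identical at 4.07, from 58 reads each. The remaining genes were lron-7 (4.06), the calmodulin-like gene cal-5 (4.02), the dehydrogenase gene dhs-25 (4.01), fkb-3 (4.004), rpl-7A (3.92) and C15H9.9 (3.81). Equal folds come from equal read numbers over the same floor.

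rpl-7A, a gene of the large ribosomal subunit, stood apart from other well-covered genes. Its region at chromosome IV, 4389240 to 4390411, had the largest −log10 q of the list, 289.6, from 1071 reads over 273. Of the 218 regions with a control level above 100, it had the highest fold, and the next was 2.68. The region overlaps 2 annotated snoRNAs, and its summit at position 4390218 lies inside 1 of them, Y24D9A.9. This feature was singled out after its values were seen. Without strand, reads of the host gene and of the snoRNA cannot be separated here.

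The gene lists ask which kinds of transcript were represented. Of 19 lists, 10 held more genes with a region than expected from all protein-coding genes after adjustment, and 0 held fewer. Without adjustment 11 lists had p under 0.05. With at least 2 regions required per gene, which favours long genes, only the chaperone list was called. The cuticle collagens, the structural proteins of the worm's exoskeleton, led: 77 of 174 genes (44.3%, interval 36.7 to 51.96) carried a region, with an odds ratio of 17.1 (12.4 to 23.5, Fisher adjusted p = 1.1e-53). Without regions over 2 genes, 60 of the 174 remained (odds ratio 12.7, Fisher's exact adjusted p = 3.7e-37). In the 603 regions with the highest folds 11 of the 174 remained (odds ratio 2.54, Fisher's exact adjusted p = 0.039). Highest by fold were col-162, col-135 (3.51), col-34 (3.31) and col-49 (2.91). Their folds were otherwise small: the median over the 79 regions was 1.67, over a median control level of 350. The median of the other 1128 regions was 2.14 over 21.7, and no p-value is given, since the folds that pass depend on coverage. Collagen genes resemble each other in sequence, and how shared reads were counted is not given in the sources used here.

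**Figure D2:**
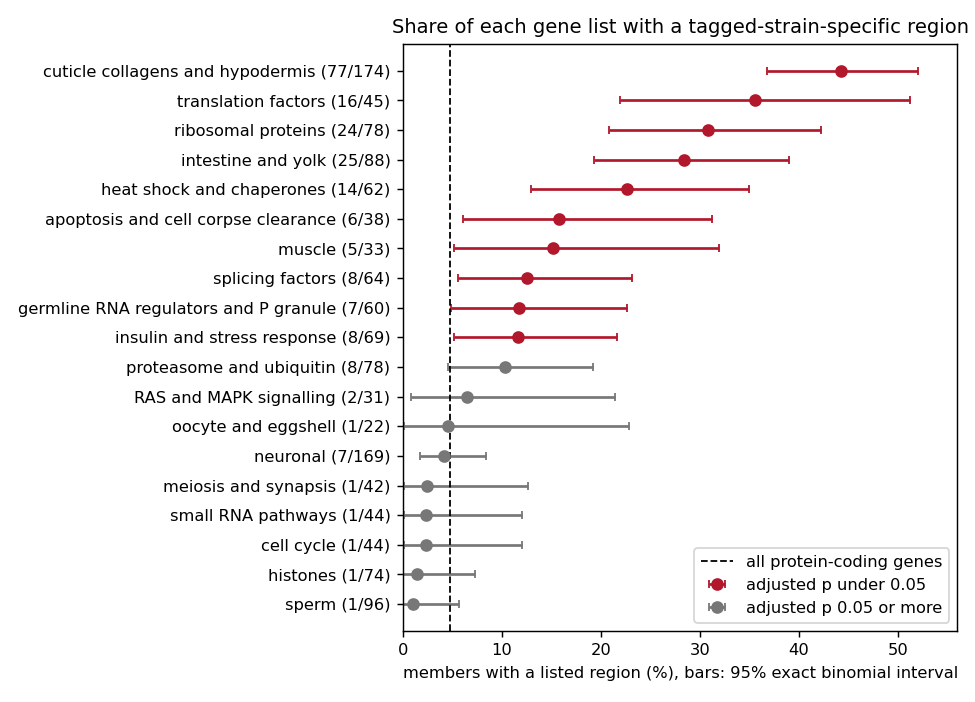
Percentage of each fixed gene list's members that carry a region (x axis), one list per line with its counts, and exact 95% binomial intervals as bars. The dashed line marks the 4.77% of all protein-coding genes, and the cuticle collagens lie farthest to the right at 44.3%.

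Genes of the translation machinery formed a further large group. Ribosomal proteins carried regions in 24 of 78 genes (30.8%, odds ratio 9.07, 5.33 to 14.995, Fisher's exact adjusted p = 9.5e-13), with rpl-7A, rps-2 (2.05), rpl-28 (1.75) and rpl-11.2 (1.70) highest. Their median fold was 1.60 over a control level of 614, and folds under 1.86 occur in the list only above the control floor. No comparison with genes of equal coverage was made, so high coverage stays open as an explanation for this list. In the 603 regions 1 of the 78 remained, giving an odds ratio of 0.48 (Fisher's exact adjusted p = 0.92). Translation factors carried regions in 16 of 45 genes (35.6%, odds ratio 11.2, 5.65 to 21.3, Fisher's exact adjusted p = 5.4e-10). Genes of initiation factors led these: eif-3.G at 3.25, eif-3.I at 3.04, eif-1 at 2.899 in a region shared with pigb-1, and eif-2beta at 2.27. In the 603 regions 4 of the 45 remained (odds ratio 3.65, Fisher's exact adjusted p = 0.094). The median fold over the 19 regions of translation factors was 1.67 over a control level of 43.4, so coverage stays open here too. The heat shock and chaperone list had 14 of 62 genes (22.6%, odds ratio 5.89, 2.99 to 10.9, Fisher's exact adjusted p = 3.8e-06). It was led by the cytosolic chaperonin genes cct-3 (2.67) and cct-5 (2.48), dnj-16 (2.48) and the mitochondrial chaperone hsp-60 (2.47). The median fold over this list's 19 regions was 1.96 over a control level of 24.9. No comparison at equal coverage was made for this list either.

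Of the tissue lists besides the collagens, those of intestine and muscle were called and the neuronal list was not. The intestine and yolk list had 25 of 88 genes (28.4%, odds ratio 8.10, 4.86 to 13.1, Fisher's exact adjusted p = 1.5e-12). fat-4, spp-8 (4.07), the acid phosphatase gene pho-1 (3.45) and the aspartyl protease gene asp-14 (2.69) were highest, each at the control floor. In the 603 regions 10 of the 88 remained (odds ratio 4.84, Fisher's exact adjusted p = 0.0019). The median fold over the list's 30 regions was 1.77 over a control level of 99.3, and no comparison at equal coverage was made. The muscle list had 5 of 33 genes (odds ratio 3.57, 1.08 to 9.41, Fisher's exact adjusted p = 0.040): pat-3, a beta integrin, at 3.38, unc-60 at 2.28, unc-52, the basement membrane protein perlecan, at 2.13, and unc-87 at 1.81 were the highest. It was not called against gene sets matched on span (permutation adjusted p = 0.17) or in the 603 regions (Fisher's exact adjusted p = 0.13). The neuronal list had 7 of 169 genes (4.14%, odds ratio 0.86, 0.34 to 1.82, Fisher's exact adjusted p = 0.90). They were led by flp-28 (3.04, in a region that overlaps W07E11.1 more), nlp-27 (2.73), nlp-24 (2.51) and eat-4 (2.30, in a region shared with ZK512.7).

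Of the germline lists, the RNA regulators were called and the others were not. Meiosis and synapsis had 1 of 42 genes, brc-1, with a fold of 2.14. Oocyte and eggshell had 1 of 22, perm-2, at 1.36. The sperm list had 1 of 96, msp-31, at 1.71, in a region that overlaps aagr-2 more. Their Fisher's exact adjusted p-values were 0.81, 1 and 0.15. The germline RNA regulator and P granule list had 7 of 60 genes (11.7%, odds ratio 2.65, 1.01 to 5.86, Fisher's exact adjusted p = 0.045). Its leading members were gla-3 (3.73), cey-1 (2.502), atx-2 (2.48) and puf-7 (2.24). The region of gla-3 overlaps dhs-3 more, and with regions over 2 genes left out the list was no longer called (Fisher's exact adjusted p = 0.071), nor was it against span-matched sets (permutation adjusted p = 0.096).

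Smaller groups also carried regions. The apoptosis and cell corpse clearance list had 6 of 38 genes (odds ratio 3.76, 1.28 to 9.14, Fisher's exact adjusted p = 0.028). Highest were gla-3, the nuclease gene nuc-1 (3.48), lin-35 (2.93, shared with C32F10.4) and pmk-3 (1.93), and the list was no longer called without regions over 2 genes (Fisher's exact adjusted p = 0.12). Splicing factors had 8 of 64 genes (odds ratio 2.86, 1.18 to 6.06, Fisher's exact adjusted p = 0.029), led by rsp-8 (2.40), prp-39 (2.28), rsp-6 (2.19) and rsp-4 (2.07). The insulin and stress list had 8 of 69 (odds ratio 2.63, 1.08 to 5.54, Fisher's exact adjusted p = 0.040), led by gst-1 (3.01), gst-7 (2.47), ctl-2 (2.42) and daf-16 (2.35). Against span-matched sets the permutation adjusted p of these 3 lists was 0.093, 0.084 and 0.10. The proteasome and ubiquitin list had 8 of 78 (odds ratio 2.29, Fisher's exact adjusted p = 0.056), with pas-6 (3.38), ubc-13 (2.42), ubc-3 (2.24) and rpn-8 (2.21) highest. It was called without regions over 2 genes (Fisher's exact adjusted p = 0.037).

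The remaining lists were near or below the overall share and none passed the test. RAS and MAPK signalling had 2 of 31 genes, par-1 (2.36) and mek-2 (2.17), and the region of mek-2 also covers the collagen gene col-48. Cell cycle had 1 of 44 (lin-35), small RNA pathways 1 of 44 (prg-1, 1.94) and histones 1 of 74 (his-35, 3.51). The upper 95% limits of the odds ratios were 5.45, 2.73, 2.73 and 1.57, in that order.

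**Figure D3:**
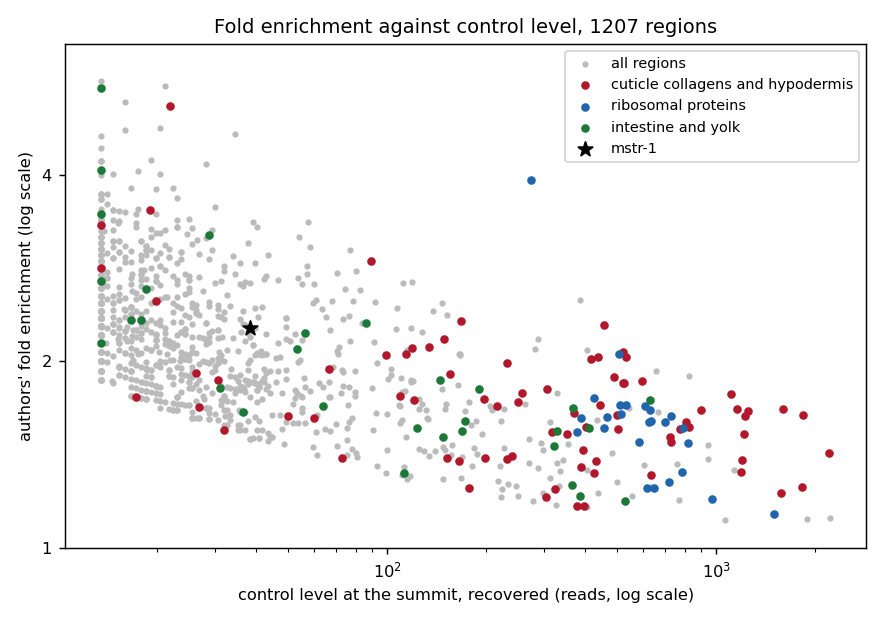
The authors' fold enrichment (y axis, log scale) against the control level at the summit recovered from the fold and p-value (x axis, reads, log scale) for 1207 regions, with regions of 3 gene lists and of mstr-1 marked. The lowest fold present falls from 1.86 at the control floor of 13.49 to 1.11 at control levels above 300, where many collagen and ribosomal protein regions lie.

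By chromosome, genes of III were represented most and genes of V least. III held 238 regions where 160 were expected from its number of protein-coding genes (ratio 1.49, Fisher adjusted p = 5.7e-09), V held 212 against 302 (0.70, adjusted p = 5.7e-09) and II 167 against 208 (0.80, adjusted p = 0.0037). I, IV and X had ratios of 1.12, 1.13 and 1.03 with adjusted p of 0.12, 0.069 and 0.67. In the 603 regions with the highest folds IV was called (ratio 1.302, Fisher's exact adjusted p = 0.0036). The overall chi-square was 79.7 (simulated p = 1e-05, the smallest the draws can give). Regions of the same gene are not independent, and the background includes genes not expressed in these worms. With each gene counted once, the ratio was 1.43 for III, 0.73 for V and 0.80 for II (Fisher's exact adjusted p = 1.2e-06, 1.2e-06 and 0.0075). Against bases in gene spans the ratio was 1.296 for III (exact binomial adjusted p = 1.5e-04), while V and II no longer passed (0.87 and 0.90, adjusted p = 0.085 and 0.21).

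Few regions lay in non-coding genes alone. The 8 regions outside protein-coding genes lay in 5 pseudogenes and 3 non-coding RNA genes. Highest was tts-1, annotated as non-coding RNA, with a fold of 3.35 from 195 reads over 57.4, at chromosome X, 1504339 to 1504623. lep-5, a long non-coding RNA, had 2.16 and W05H9.3 had 1.93. The pseudogenes were F07H5.3 (2.78), F07H5.5 (2.09), Y73B3A.18 (2.74), prg-2 (2.28) and C14B1.7 (1.86). These were named because the group is small, after their values were seen. No rRNA gene of the 22 annotated overlapped a region.

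Genes with a region were longer. Their median span was 2361.5 bp, against 2005 bp for all protein-coding genes (difference 356.5 bp, permutation p = 1e-05, the smallest possible). The 745 genes with exactly 1 region had a median of 1889 bp, a difference of −116 bp (permutation p = 0.11), and the 209 genes with 2 or more had a median of 5066 bp. For genes of the 603 regions the difference was 879 bp. The genes with most regions, chosen after their values were seen, were unc-52 and the filamin gene fln-1 with 7 each, and the ankyrin gene unc-44 and hecd-1 with 6 each.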

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

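The tests of the unlabelled column were chosen after its values had been seen. That column, which no comparison above uses, was above 0 for 299 of 1207 regions (24.8%): it was 1 in 287 regions and 2 in 12, and it is described here because its meaning is unstated. A count of overlapping regions in a further region list, such as that of the other replicate, is a candidate explanation. The 12 regions with the value 2 had a median width of 1141 bp against 629.5 bp at 0, a difference of 511.5 bp (permutation p = 0.026), which such a count would give. The 287 regions with the value 1 had a median of 663 bp, near that at 0. Coverage at the summit differed too: the median pileup was 193 reads above 0 and 46 at 0, a difference of 147 (permutation p = 1e-05, the smallest the permutations can give). The median fold was lower above 0, 1.81 against 2.18. Neither test can say what the column was computed against, and no biological explanation was tested.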

How the results depend on the processing

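The alternatives by unlabelled value, control floor, regions over 2 genes, whole regions, bases in gene spans, genes counted once, genes with 1 region and the span of genes in the 603 regions with the highest folds were chosen after seeing the data. No paired analysis was possible because the deposited table holds no value per library. For the same reason no replicate could be left out, and the planned interaction test and its alternatives were not run. Placement in exons, UTRs and introns and exonic length were not run either. Merging left 1207 regions. Keeping the 603 regions with the highest folds leaves fewer by construction. Regions wholly inside a gene were 98.3%. Of the 3 chromosomes called, 1 remained against bases in gene spans. The ratio of I became 0.95 there, and that of X became 0.91 there and 0.99 in the 603 regions, where IV gained the call (1.302). The 10 called lists became 5 against span-matched sets, 4 in the 603 regions, 1 with at least 2 regions per gene, 5 with an unlabelled value of 1 or 2 and 5 above the control floor. The chaperone list was called under all 7 alternatives (odds ratio or matched ratio 4.62 to 8.48, Fisher's exact or permutation adjusted p 9.1e-07 to 0.011). None of the 7 matched genes on expression or coverage, so both stay open for this list. Collagen and intestine lists were called under 6 of 7 each, failing only with at least 2 regions per gene (Fisher's exact adjusted p = 0.69 and 0.087). Genes with 2 or more regions had a median span of 5066 bp, against 1220 bp for the collagen list. For collagens this failure therefore cannot be told apart from an effect of span. Ribosomal proteins and translation factors were called under 5 of 7 each, insulin and stress under 3, splicing factors and muscle under 2 each, and germline RNA regulators and apoptosis under 1 each. The alternatives are not independent, so these counts do not measure support. The rule of 0.5 of a region inside the gene kept 940 of 954 genes. At the control floor lay no ribosomal protein region and 2 of 79 collagen regions, so leaving out the floor could hardly remove these lists. Regions with an unlabelled value above 0 had a median pileup of 193 reads against 46, so that choice favours well-covered genes. Reversals among lists were ribosomal proteins at 0.48 and neuronal at 1.37 in the 603 regions. With at least 2 regions per gene, splicing factors and proteasome had an odds ratio of 0, meiosis 2.31 and small RNA pathways 2.21. Proteasome was also 0 with an unlabelled value of 1 or 2. Oocyte and eggshell was 1.07 without regions over 2 genes, 3.38 with an unlabelled value of 1 or 2 and 1.23 above the floor. RAS and MAPK was 0.94 against span-matched sets and 0.75 without regions over 2 genes. The span difference of genes with 1 region was −116 bp. For ribosomal proteins, the cut by fold also removes mostly highly covered regions. Beyond this and fewer genes entering, the cause of these changes was not tested. Over single lists and chromosomes, 102 of 151 alternative values kept direction and call, 32 lost the call, 2 gained it and 15 changed direction. Depth limits the list: the lowest fold at the control floor was 1.86.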

Other observations

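The name classes, the snoRNA overlaps and the germline contrast were tested after the results were seen, while the collagen tests were set before their results. Gene families, tested by name without a prior list, added the vacuolar proton pump. Of 183 name classes with at least 10 protein-coding members, 8 held more genes with a region than expected and 3 fewer (Fisher, Benjamini-Hochberg over the 183). Of the 183 classes, 0 were called in the 603 regions with the highest folds. The vha class, subunits of the vacuolar H+-ATPase that acidifies organelles and the gut lumen, had 14 of 20 genes (70%, odds ratio 47.2, 16.99 to 150.2, Fisher's exact adjusted p = 7.9e-13). vha-19 (2.76), vha-17 (2.32) and vha-10 (2.23) were highest, and the median fold was 1.80 over a control level of 49.5. That median is under the lowest fold at the control floor, 1.86, so high coverage stays open for this class too. Of the 20 genes, 3 remained in the 603 regions (Fisher's exact adjusted p = 0.30). The lec class of galectins had 4 of 12 genes (Fisher's exact adjusted p = 0.031), with lec-4 at 2.83, and 2 of the 12 in the 603 regions (adjusted p = 0.49). The other higher classes were col, rpl, rps, eif, the lysozymes (lys, 5 of 10) and the aspartyl proteases (asp, 7 of 17), which the lists above cover. The lower ones were the chemoreceptor classes srh (0 of 220, Fisher's exact adjusted p = 0.0014) and str (0 of 193, adjusted p = 0.0026) and the F-box class fbxa (0 of 170, adjusted p = 0.0077). Every listed region held at least 26 reads at its summit, and the background includes genes not expressed in these worms. Low expression and a lack of association with MSTR-1 therefore cannot be told apart for these classes.

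snoRNA genes overlapped 13 regions, and in 2 of these the summit lay inside the snoRNA. Of 346 annotated snoRNA genes 15 (4.34%) were overlapped. Against all annotated genes this class was not called (odds ratio 1.85, 1.02 to 3.11, Fisher's exact adjusted p = 0.067). Besides rpl-7A this was cdc-48.1, with a fold of 3.14 from 85 reads over 26.4 and its summit in C06A1.9. nol-56 had 3.28 with 2 snoRNAs inside its region and the summit in neither. These genes were named after their values were seen.

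Gene length does not account for the over-representation of cuticle collagens: 77 genes carried a region where 8.49 were expected in 10000 gene sets matched on span, a ratio of 9.07. Calling of small folds on well-covered transcripts stays open. The median fold of collagen regions differed from that of the other regions by −0.47, but this decides nothing, since the lowest fold listed was 1.86 at the control floor and 1.11 at control levels above 300. No comparison with genes of equal coverage that lack a region was made. A difference in stage or moulting cycle between the worms compared stays open, since 13 of 214 other cuticle and moulting genes carried a region (odds ratio 1.29, 0.67 to 2.27, Fisher's exact p = 0.33), an interval too wide to decide; association of these mRNAs with MSTR-1 stays open too, as no N2 library was analysed here.

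The 4 germline lists together had 10 of 220 genes with a region (4.55%), and the muscle, intestine, collagen and neuronal lists 114 of 464 (24.6%, Fisher's exact p = 6.3e-12). The collagen list alone does not account for this: without it the somatic share was 12.8% (37 of 290, Fisher's exact p = 0.0017). The intestine list by itself had 25 of 88 (28.4%, Fisher's exact p = 2.5e-08), but it was picked as the highest of the remaining somatic lists. With 1 germline list left out at a time, the intestine share stayed higher (Fisher's exact p from 5.7e-10 to 4.8e-05). The somatic share without collagens stayed higher without RNA regulators, meiosis or oocyte genes (Fisher's exact p = 4.0e-05, 0.0063 and 0.0024), but not past the threshold without sperm genes (12.8% against 7.26%, Fisher's exact p = 0.12). Without collagens and intestine the somatic share was 5.94% (12 of 202, Fisher's exact p = 0.66). Coverage was not matched: the median control level of listed regions was 350 for collagens, 99.3 for intestine, 36.2 for muscle and 28.1 for neuronal genes. In the germline lists it was 13.5 for meiosis (4 regions, all of brc-1), 19.1 for RNA regulators, 23.6 for the 1 sperm region and 93.2 for the 1 oocyte region. These values cover listed regions only and do not give the coverage of all genes of a list. A difference in coverage and a biological difference between tissues both stay open and untested.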
